A study of Arabidopsis thaliana with 18 samples.

How the data were processed

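Transcripts were measured by RNA sequencing in 18 libraries of Arabidopsis thaliana seedlings, Col-0 (WT) and pifq, 3 libraries each from cotyledon, apical hook and hypocotyl. Per the labels' protocols, plants grew for 4 days in continuous darkness at 22 °C on MS medium with 3% sucrose. Total RNA was extracted with Trizol, treated with DNase I and made into libraries with a NEBNext Ultra RNA kit, which does not mark strand. The titles number the replicates Bio1 to Bio3, and the labels do not otherwise state separate cultures. P-values therefore measure only the spread between these samples, which may not be that of separate cultures.

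The authors deposited 1 file per library with 1 value per gene for 26073 genes. Per the submitters' processing notes, HISAT2, DESeq2 and the TAIR10 genome were used, with no roles or versions given, and the counting tool, gene annotation and filters are not stated. The deposited values are FPKM, scaled by exon length and by the reads or read pairs of the library. The unit was read from the values, since the headers give none. Multiplied by the merged exon length of the gene in the TAIR10.1 annotation, 99.37% to 99.50% of the values below 100 reads are whole multiples of 1 step per library, with a tolerance of 0.05 reads. That step gives the library's denominator, 12955815 to 20701103 reads or read pairs, and covers 25788 genes. The other 285 did not match the annotation: 128 chloroplast, 108 mitochondrial and 49 ENSRNA entries. Gene names come from the same annotation by locus tag, and coordinates are TAIR10.1, from that match.

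The design fixed before the data were examined named a quasi-likelihood count test as the main test, with limma for files of normalised values. The files hold FPKM, so limma 3.58.1 in R 4.3.3 was used for the values reported, with a trend, on log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were tested, 19349 in all, in 1 fit of 6 group means without a block. Fold changes are on the scale of log2(FPKM + 1), which understates the change of low genes. A gene is called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. Adjusted p-values of genes are from limma throughout. The contrasts were pifq against WT in each organ, the differences of these effects between organs, 1 test over all organs, and organ against organ within each genotype. On data simulated for pifq against WT in cotyledon over 18001 genes, the fit recovered 43.3% of 67 genes changed 1.5-fold, 73.1% of 67 changed 2-fold and 93.9% of 66 changed 4-fold. It called 6 of 17801 unchanged genes. The simulated libraries shared 1 mean per gene apart from these changed genes and had no shifts of scale. They therefore do not show how many false calls such shifts give. Median-ratio factors of the real libraries ran from 0.815 to 1.236.

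The 25 gene lists, with 431 members named by AGI code and every chloroplast-encoded gene, were also fixed then from general knowledge. They cover light-harvesting, photosystem, chlorophyll, Calvin cycle and carotenoid genes, genes induced by PIFs in the literature, and light signalling regulators. Further lists hold Aux/IAA and GH3, SAUR, auxin synthesis and transport, ethylene and hook, brassinosteroid, gibberellin, cell wall, flavonoid, clock, seed reserve, cell cycle and chloroplast-encoded genes. The marker lists are embryo storage, meristem and boundary, root, stomatal lineage, xylem and shoot epidermis. Each list was tested per organ with camera of limma at a preset correlation of 0.01, again with an estimated correlation, and with fry. Both were adjusted over all lists and organs, and list adjusted p-values are from camera. Camera compares a list with all other genes tested, so a list said to rise or fall does so relative to them. Its direction can therefore differ from the sign of the list's median. LHCB1.5 and F3H are not analysed here.

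Genes named in the text follow a rule of the same date. It takes the PIF loci and 14 fixed genes, and for each organ the 6 largest rises and falls among called genes with groups that do not overlap. It takes up to 2 called rises and falls of each list and organ. It also takes the 6 largest interactions per pair of organs, up to 6 genes called in opposite directions, and the 5 strongest markers of each organ in WT. A minimum of 10 CPM in that rule was applied as FPKM multiplied by the gene's length in kilobases. The rule named 186 genes, of which 1 is not reported here. Genes with near-identical copies, such as LHCB1.1 to LHCB1.3, LHCB2.1 and LHCB2.2, RBCS1B, RBCS2B and RBCS3B, and SAUR19 to SAUR24, are uncertain, since the counting of shared reads is not stated. Without strand, reads of a gene and of an overlapping antisense gene cannot be separated.

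Alternatives were a pseudocount of 0.1, no filter on low values, a stricter filter, removal of organelle-encoded genes, only the 6 libraries compared, a replicate block, each library left out in turn, and the other list tests. Chosen after seeing the data were median-ratio scaling, limma-voom at median-ratio factors on the reads recovered from the steps, the organelle-encoded share of each library as a covariate, and leaving out pifq hook replicate 2 with pifq hypocotyl replicate 3. Other splits of the libraries were refitted, all 10 for 3 against 3 and 100 drawn with a fixed seed otherwise.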

Results

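RNA sequencing measured transcript levels in cotyledons, apical hooks and hypocotyls of Arabidopsis thaliana seedlings grown for 4 days in continuous darkness. Wild-type Col-0 (WT) was set beside pifq, a mutant in PIF1, PIF3, PIF4 and PIF5. These genes encode basic helix-loop-helix transcription factors that hold back light development in the dark. The 2 genotypes and 3 organs make 6 groups of 3 libraries, 18 in all, and each library lists 26073 genes. Whole-read steps in the low values put the reads or read pairs behind a library at 12955815 to 20701103, so that one of them in a gene of 1 kb was worth 0.0483 to 0.0772 FPKM. Levels are given throughout in FPKM, as mean ± SD of 3 libraries. For every gene said to rise or fall between the genotypes with its levels, all 3 pifq libraries lay on one side of all 3 WT libraries.

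Organ and genotype each set the libraries apart. The first principal component held 50.4% of the variance and ran from pifq cotyledons (-93.9 to -90.5) to WT hypocotyls (104.6 to 117.7). The second held 26.1% and placed all 9 WT libraries at -18.5 or below and all 9 pifq libraries at 31.6 or above. On the first component pifq hook replicate 2 lay at -19.1, while replicates 1 and 3 lay at -53.3 and -54.8.

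**Figure D1:**
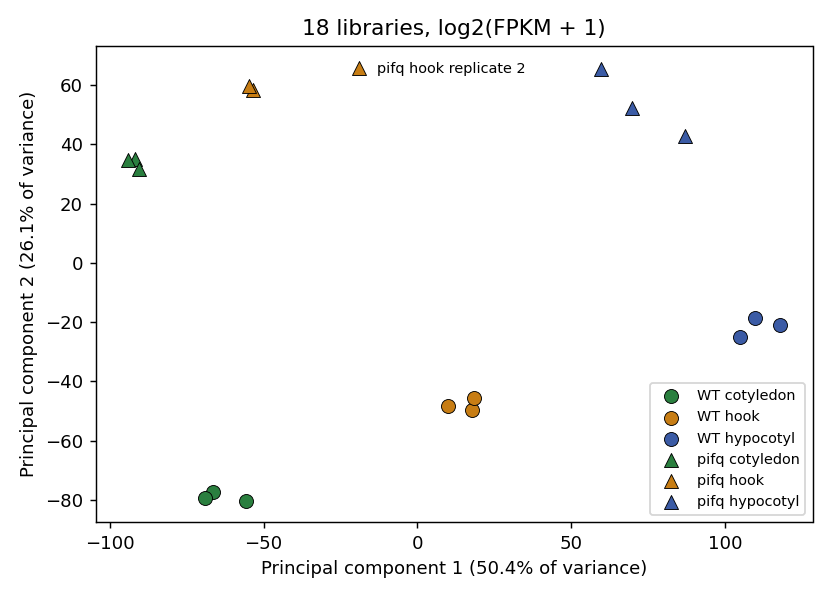
Scores of the 18 libraries on principal components 1 (x axis, 50.4% of variance) and 2 (y axis, 26.1%) of log2(FPKM + 1), coloured by organ, with circles for WT and triangles for pifq. WT libraries lie at -18.5 or below on component 2 and pifq libraries at 31.6 or above, and the labelled pifq hook replicate 2 lies at -19.1 on component 1.

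Transcripts encoded in the chloroplast and mitochondrial genomes differed widely between libraries. Summed chloroplast-encoded FPKM had a median of 14376 in WT and 908 in pifq cotyledons, and of 7951 and 636 in hooks. In hypocotyls the medians were 2433 and 2867, and the pifq libraries there spread from 316 to 4307. Median mitochondrion-encoded FPKM in pifq was 0.0183 of that in WT in cotyledons, 0.00927 in hooks and 0.256 in hypocotyls. In hypocotyls the 2 genotypes overlapped, with a 21.2-fold spread among pifq libraries, and the ratio was 0.141 without pifq hypocotyl replicate 2 and 0.415 without pifq hypocotyl replicate 3. This organelle share moves with genotype in cotyledons and hooks, and therefore with each nuclear gene group that rose or fell there.

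**Figure D2:**
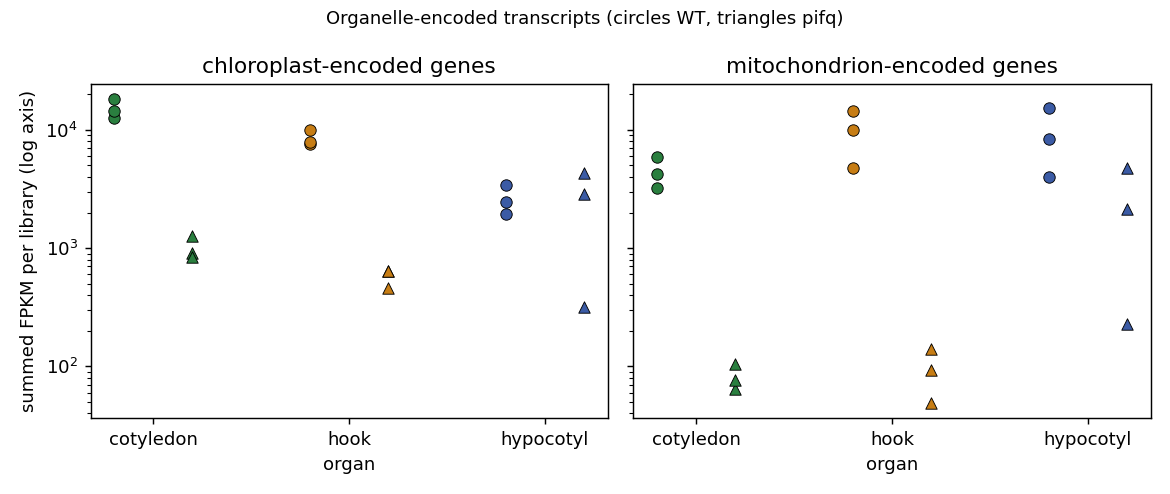
Summed FPKM of chloroplast-encoded (left) and mitochondrion-encoded (right) genes in each library on a log axis, by organ, with circles for WT and triangles for pifq. Chloroplast-encoded sums in pifq hypocotyls spread from 316 to 4307, while those of pifq cotyledons and hooks lie below every WT library.

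The targeted loci come first, since they check the labels (coordinates from TAIR10.1). PIF3 (AT1G09530, chromosome 1, 3075768 to 3079654) fell in cotyledons from 54.4 ± 2.81 to 3.16 ± 0.437. It fell in hooks from 87.7 ± 3.29 to 2.0 ± 0.191 and in hypocotyls from 51.8 ± 10.3 to 3.91 ± 0.699. PIF5 (AT3G59060, chromosome 3, 21827905 to 21830837) fell in cotyledons from 13 ± 2.07 to 3.29 ± 0.416. In hooks it fell from 15.9 ± 0.346 to 3.85 ± 0.565 and in hypocotyls from 8.12 ± 1.61 to 4.45 ± 0.718. PIF4 (AT2G43010, chromosome 2, 17886101 to 17889087) was not called in cotyledons (10.4 ± 1.42 and 11.5 ± 2.69, adjusted p = 0.632) or hooks (14.4 ± 0.621 and 17 ± 2.7, adjusted p = 0.319). It rose in hypocotyls from 6.3 ± 1.73 to 18.9 ± 2.68. PIF1 (AT2G20180, chromosome 2, 8704024 to 8707009) was not called in cotyledons (10.6 ± 0.863 and 8.9 ± 0.639, adjusted p = 0.335), fell in hooks from 20.3 ± 0.956 to 12.1 ± 3.12 and rose in hypocotyls from 8.42 ± 3.01 to 17.2 ± 1.06. The labels do not give the alleles, and a value over a whole gene can include reads of a disrupted transcript, so PIF1 and PIF4 check nothing. PIF7 (AT5G61270, chromosome 5, 24638491 to 24640765), a relative outside the quadruple mutant, rose in cotyledons from 0.288 ± 0.030 to 8.36 ± 0.343, in hooks from 0.897 ± 0.0546 to 12.7 ± 1.12 and in hypocotyls from 0.267 ± 0.186 to 6.36 ± 1.71.

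**Figure D3:**
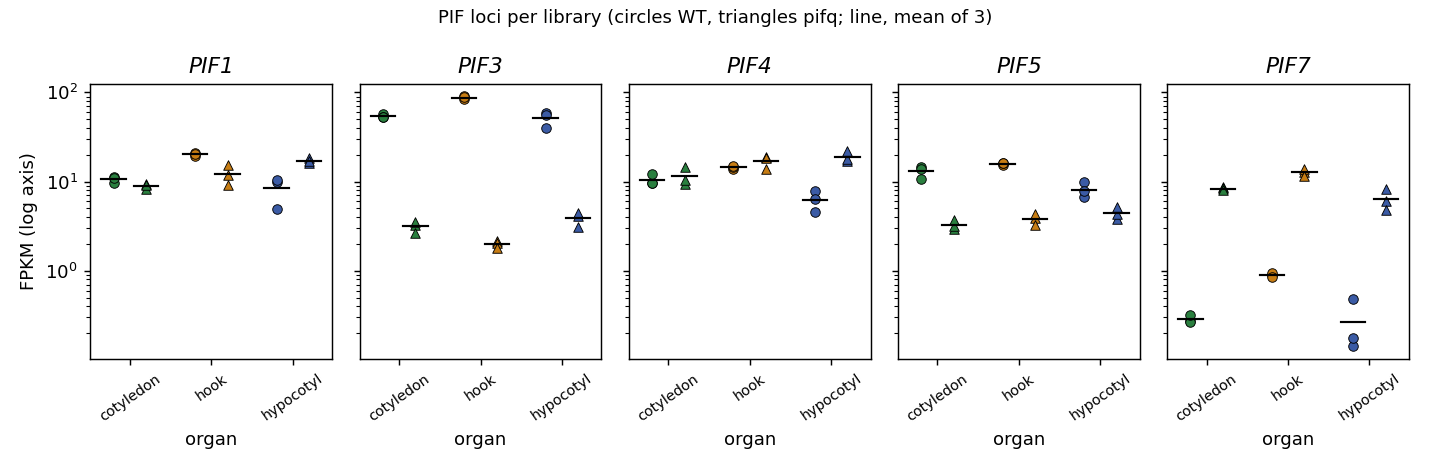
FPKM on a log axis of PIF1, PIF3, PIF4, PIF5 and PIF7 in each library by organ, with circles for WT, triangles for pifq and a line at the mean of 3 libraries. PIF3 means lie at 51.8 to 87.7 in WT and 2.0 to 3.91 in pifq, and PIF7 means at 0.267 to 0.897 and 6.36 to 12.7.

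Cotyledons of pifq and WT were compared to ask which transcripts of the organ that will green depend on these factors in the dark. Genes of the photosynthetic apparatus stood far higher in pifq. LHCB1.4, for a chlorophyll-binding antenna protein of photosystem II, rose from 142 ± 36 to 6870.4 ± 705 (log2 change 5.61, adjusted p = 4.4e-10). Of 20 light-harvesting genes, 18 rose, 1 fell and 1 was not called (adjusted p = 0.434 with an estimated correlation), and LHCB7 fell from 18.2 ± 3.05 to 11.5 ± 0.654. Of 30 nuclear photosystem core and electron transport genes, 29 rose, 0 fell and 1 was not called (adjusted p = 0.434 with an estimated correlation). PSAN, of photosystem I, rose from 169 ± 17.2 to 1585 ± 229. Of 20 Calvin cycle genes, 16 rose, 1 fell and 3 were not called (adjusted p = 0.523 with an estimated correlation), and GAPA2 led with a rise from 202 ± 15.2 to 1316 ± 152. Of 15 carotenoid genes, 10 rose, 1 fell and 4 were not called (11 rose and 1 fell adjusted over the list alone; adjusted p = 0.523 with an estimated correlation). The phytoene synthase gene PSY rose from 107 ± 8.57 to 288 ± 0.791.

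Chlorophyll synthesis genes of the cotyledon rose too: of 28, 20 rose, 2 fell and 6 were not called (adjusted p = 0.51 with an estimated correlation). HEMA1, for the first committed enzyme of the pathway, rose from 128 ± 11.3 to 621 ± 8.24, and CHLH, for a subunit of magnesium chelatase, from 238 ± 14.4 to 848 ± 80.1. The protochlorophyllide oxidoreductase genes split, PORA falling from 1583 ± 94.3 to 206 ± 21.7 and PORB from 2126 ± 80.5 to 1189 ± 28.8 while PORC rose from 55 ± 6.64 to 168 ± 2.24. Values of the 119 chloroplast-encoded genes were lower, as 0 rose, 108 fell and 11 were not called (adjusted p = 0.51 with an estimated correlation). Adjusted over the list alone, 0 rose and 111 fell. Median mitochondrion-encoded sums fell there too, to 0.0183 of WT, and those of nuclear small RNA to 0.216. Less carry-over of RNA without a poly(A) tail may therefore account for part of this fall, which cannot be read as a response of the chloroplast alone.

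Cell division genes of the cotyledon rose. All 17 cell cycle genes were called (adjusted p = 0.0763 with an estimated correlation), and KN, for a syntaxin of the forming cell plate, rose from 4.77 ± 0.244 to 29.4 ± 2.33. Of 11 stomatal lineage markers, 9 rose, 0 fell and 2 were not called (adjusted p = 0.434 with an estimated correlation), and the polarity gene BASL rose from 0.535 ± 0.0944 to 9.74 ± 0.486. Of 17 flavonoid genes, 8 rose, 3 fell and 6 were not called (adjusted p = 0.51 with an estimated correlation), and DFR, of anthocyanin synthesis, rose from 2.07 ± 0.942 to 35.7 ± 5.27. Seed reserve mobilisation genes fell, since of 12, 1 rose, 11 fell and 0 were not called (adjusted p = 0.434 with an estimated correlation). ICL, for the isocitrate lyase of the glyoxylate cycle, fell from 6499.7 ± 787 to 427 ± 53.1. Embryo storage genes were not called as a list, as 0 rose, 3 fell and 5 were not called (adjusted p = 0.213; 0 rose and 2 fell adjusted over the list alone). EM1, for a late embryo protein, fell from 32.7 ± 3.57 to 0.62 ± 0.577.

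Among growth and light genes of the cotyledon, HLS1 (AT4G37580, chromosome 4, 17658594 to 17660878), needed for the apical hook, fell from 35.5 ± 1.01 to 3.11 ± 0.422. The ethylene and hook genes fell as a list: of 22, 3 rose, 14 fell and 5 were not called (adjusted p = 0.51 with an estimated correlation). SAUR genes, small auxin-responsive genes, rose as a list (9 rose, 1 fell and 12 were not called; 8 rose and 1 fell adjusted over the list alone; adjusted p = 0.547 with an estimated correlation). That call was lost with limma-voom (adjusted p = 0.0785), where the median log2 change was 1.70 in place of 0.42. SAUR50 rose from 6.05 ± 0.279 to 57.1 ± 2.98, yet SAUR17 fell from 39.8 ± 0.865 to 2.41 ± 1.13. Of the 22 genes known from the literature as induced by PIFs, 10 rose, 10 fell and 2 were not called (adjusted p = 0.779). Their median log2 change of 0.03 stood against a mean of -0.77 and a test pointing downward. XTH15, a cell wall enzyme gene, fell from 939 ± 70.3 to 3.5 ± 2.2, and HFR1, for an atypical helix-loop-helix protein, from 29.1 ± 3.07 to 1.49 ± 0.295. PIL1 fell from 4.05 ± 0.907 to 0.764 ± 0.349, and PRE1, for a growth-promoting regulator, rose from 0.41 ± 0.437 to 11 ± 0.87. Of 28 light signalling regulators, 7 rose, 15 fell and 6 were not called (adjusted p = 0.213). HY5, for a bZIP regulator of light development, fell from 57.9 ± 8.32 to 24.7 ± 3.92, and BBX25 rose from 22.2 ± 1.46 to 135 ± 11.5.

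Further lists of the cotyledon were not called. Aux/IAA and GH3 genes gave 8 rises and 3 falls among 17 (adjusted p = 0.111, but 0.0451 without WT cotyledon replicate 3), and IAA19 rose from 1.87 ± 1.94 to 5.75 ± 0.765. Auxin synthesis and transport genes gave 6 rises and 4 falls among 17 (adjusted p = 0.136), or 7 and 4 adjusted over the list alone. After median-ratio scaling 10 of them rose and 3 fell. The list was called upward with fry (0.0468) and with the organelle-encoded share as a covariate (0.0206). YUC8, for an auxin synthesis enzyme, was not called (3.36 ± 0.767 and 4.21 ± 0.488, adjusted p = 0.159, but 0.0194 after median-ratio scaling and 0.0221 with limma-voom). Gibberellin genes gave 3 rises and 7 falls among 19 (adjusted p = 0.536). Brassinosteroid genes gave 6 rises and 7 falls among 16 (adjusted p = 0.849), with a median of -0.13 against a mean of 0.05 and a test pointing upward. Cell wall expansion genes gave 6 rises and 11 falls among 28 (adjusted p = 0.867), and EXPA5, an expansin gene, rose from 1.62 ± 1.09 to 21.6 ± 0.472. Clock genes gave 5 rises and 8 falls among 14 (adjusted p = 0.433). The clock gene LHY rose from 16.3 ± 4.68 to 158 ± 5.04, and ELF4 fell from 69.5 ± 11.2 to 3.79 ± 1.39.

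Of 8 meristem and boundary markers in cotyledons, 0 rose and 4 fell (adjusted p = 0.148), and the meristem gene STM fell from 4.11 ± 1.21 to 0.603 ± 0.325. Xylem markers gave 1 rise and 2 falls among 10 (adjusted p = 0.867; 1 rose and 1 fell adjusted over the list alone), with a median of -0.14 under a test pointing upward. The 4 root and 3 shoot epidermis markers held no called gene (adjusted p = 0.867 and 0.849). The root list had a median of -0.06 under a test pointing upward.

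Of the 19349 genes tested in cotyledons, 4718 were higher in pifq, 1736 of them by at least 2-fold. Another 6847 were lower, 2114 of them by at least 2-fold, and 7784 were not called. QQS, a starch regulator gene, rose from 0.763 ± 0.661 to 127 ± 8.68, and LOX2, a plastid lipoxygenase gene of jasmonate synthesis, from 0.0138 ± 0.0123 to 77.6 ± 16.4. Of the calls, 40.8% were higher in pifq on the deposited scale and 54.9% after median-ratio scaling, which moved the median log2 change of all genes from -0.098 to 0.042. With the organelle-encoded share of each library as a covariate, carotenoid genes (adjusted p = 0.0729, median log2 change 0.26 in place of 0.52), chloroplast-encoded genes (0.121, -0.39 in place of -3.01) and IAA19 (0.397, 0.87 in place of 1.44) lost their calls in this organ. That share includes the chloroplast-encoded values themselves, so in no organ can the covariate test that list. Over all genes, 5553 of the 11565 calls in cotyledons were kept in the same direction with this covariate. Among named genes over the 3 organs, 38 calls were lost with it, and not all of them are given here. Over the 3 organs, camera with its preset correlation called 45 of 75 list tests and with an estimated correlation 0, of which 6 had an unadjusted p under 0.05, while fry called 56. Apart from lists named with fry elsewhere, it added clock genes (cotyledon and hook), meristem and boundary markers (all 3 organs), epidermis and root markers (hook), flavonoid and light signalling genes (hypocotyl), and PIF-induced, gibberellin, light signalling and embryo storage genes (cotyledon). Adjusted over the list alone, the counts of rises and falls were those over all genes in every list and organ except where another count is given. After median-ratio scaling the counts of many lists moved, and they are given for some lists only.

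Hooks were compared to ask what the bent upper stem, closed in dark-grown WT seedlings, expresses without these factors. HLS1 fell from 19.4 ± 4.91 to 2.66 ± 0.0187, and ARL, an organ growth gene, from 83.8 ± 9.29 to 11.2 ± 0.988. Of the 22 ethylene and hook genes, 3 rose, 17 fell and 2 were not called (adjusted p = 0.273 with an estimated correlation). Of the 19 gibberellin genes, 1 rose, 13 fell and 5 were not called (adjusted p = 0.434 with an estimated correlation). GASA4, a gibberellin-regulated gene, fell from 12200.4 ± 1493 to 1477 ± 65.9. GA2OX8, for an enzyme that inactivates gibberellin precursors, fell from 22.8 ± 4.64 to 0.334 ± 0.279. Brassinosteroid genes fell as a list (1 rose, 10 fell and 5 were not called; 1 rose and 11 fell adjusted over the list alone; adjusted p = 0.51 with an estimated correlation), and BEE1, a brassinosteroid-responsive regulator, fell from 15.7 ± 1.44 to 5.72 ± 1.25. Cell wall expansion genes fell as a list (4 rose, 15 fell and 9 were not called; adjusted p = 0.492 with an estimated correlation). XTH15 fell from 500.4 ± 102 to 2.91 ± 0.262, although EXPA5 rose from 28.6 ± 3.7 to 142 ± 44.5.

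Genes induced by PIFs in the literature fell as a list in hooks (5 rose, 13 fell and 4 were not called; adjusted p = 0.434 with an estimated correlation). SOM, a regulator of seed germination, fell from 39.8 ± 3.69 to 0.558 ± 0.176, HFR1 from 61.7 ± 6.8 to 1.89 ± 0.307 and PIL1 from 10.4 ± 0.588 to 5.42 ± 1.43. Light signalling regulators fell as a list, as 8 rose, 17 fell and 3 were not called among 28 (adjusted p = 0.434 with an estimated correlation). HY5 fell from 109.9 ± 7.19 to 36.3 ± 6.26 and RUP1, a repressor of ultraviolet-B signalling, from 96.7 ± 7.57 to 4.57 ± 1.32, while BBX25 rose from 16.8 ± 2.31 to 114 ± 7.13. Auxin synthesis and transport genes were not called (6 rises, 8 falls, adjusted p = 0.168). TAA1, for an auxin synthesis enzyme, fell from 47.7 ± 4.77 to 11 ± 0.366. Aux/IAA and GH3 genes were not called (4 rises, 4 falls, adjusted p = 0.597), nor was IAA19 (49.1 ± 6.17 and 32.9 ± 9.12, adjusted p = 0.217). IAA19 was called lower in a fit of only the 6 libraries compared (0.0271) and with limma-voom (0.0456). SAUR genes were not called (5 rises, 4 falls, adjusted p = 0.391; 4 rose and 4 fell adjusted over the list alone). SAUR50 rose from 21.9 ± 1.91 to 54.1 ± 8.23, and SAUR17 fell from 33.1 ± 8.39 to 0.482 ± 0.516.

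The photosynthesis genes of the hook rose, as those of the cotyledon did. LHCB1.4 rose from 55 ± 15.4 to 2874 ± 455, and of the 20 light-harvesting genes, 19 rose, 0 fell and 1 was not called (adjusted p = 0.434 with an estimated correlation). All 30 photosystem and electron transport genes rose (adjusted p = 0.434 with an estimated correlation), PSAN from 84.8 ± 18.3 to 797 ± 139. Of the chlorophyll genes, 22 rose, 2 fell and 4 were not called (adjusted p = 0.51 with an estimated correlation). HEMA1 rose from 63.7 ± 8.48 to 288 ± 69.9, CHLH from 105 ± 19.6 to 456 ± 125 and PORC from 24.3 ± 3.79 to 87.6 ± 18, while PORA fell from 475 ± 168 to 72.9 ± 27.2. Of the Calvin cycle genes, 17 rose, 0 fell and 3 were not called (adjusted p = 0.523 with an estimated correlation). Of the carotenoid genes, 14 rose, 1 fell and 0 were not called (adjusted p = 0.523 with an estimated correlation). Values of the 119 chloroplast-encoded genes fell, as 0 rose, 90 fell and 29 were not called (adjusted p = 0.492 with an estimated correlation). Adjusted over the list alone, 0 rose and 92 fell. Median mitochondrion-encoded sums fell there too, to 0.00927 of WT, so this fall cannot be read as a response of the chloroplast alone.

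Cell cycle genes and stomatal markers of the hook rose as well. All 17 cell cycle genes rose (adjusted p = 0.0763 with an estimated correlation), KN from 6.14 ± 1.96 to 57.9 ± 8.07. Of the stomatal markers, 10 rose, 0 fell and 1 was not called (adjusted p = 0.434 with an estimated correlation), BASL rising from 0.25 ± 0.198 to 8.06 ± 2.0. Of the flavonoid genes, 11 rose, 2 fell and 4 were not called (12 rose and 2 fell adjusted over the list alone; adjusted p = 0.51 with an estimated correlation), DFR rising from 1.08 ± 0.624 to 71.1 ± 14.1. Seed reserve genes fell (1 rose, 10 fell and 1 was not called; adjusted p = 0.434 with an estimated correlation), ICL from 2002 ± 364 to 202 ± 72.1. Embryo storage genes fell as a list (0 rose, 5 fell and 3 were not called; adjusted p = 0.524 with an estimated correlation), a call lost after median-ratio scaling (adjusted p = 0.0796) and with limma-voom (0.154), although the median log2 change was -1.61 and -4.52 there, beside -1.65. Clock genes were not called (6 rises, 8 falls, adjusted p = 0.185), although LHY rose from 12.5 ± 3.01 to 169.8 ± 7.19 and ELF4 fell from 92.5 ± 8.99 to 2.7 ± 0.734. Meristem and boundary markers were not called (4 rises, 0 falls, adjusted p = 0.162), although the boundary gene CUC3 rose from 1.04 ± 0.463 to 5.35 ± 1.19. Xylem markers were not called (adjusted p = 0.0652), with 8 rises and 0 falls among 10, or 3 rises after median-ratio scaling. They were called upward without pifq hook replicate 1 (0.0237), with no filter on low values (0.0274) and with fry (0.00045). Shoot epidermis markers gave 2 rises among 3 (adjusted p = 0.307), and 1 of 4 root markers fell (adjusted p = 0.148).

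Across all genes tested in hooks, 7090 were higher in pifq, 2426 of them by at least 2-fold. Another 4648 were lower, 1476 of them by at least 2-fold, and 7611 were not called. BGLU18, a beta-glucosidase gene, rose from 0.801 ± 0.35 to 61.8 ± 9.01, and AT5G04120, a phosphoglycerate mutase family gene, fell from 150.5 ± 45.4 to 0.0518 ± 0.0554. Higher genes were 60.4% of the calls as deposited and 48.3% after median-ratio scaling, which moved the median log2 change from 0.119 to -0.023. With the organelle-encoded share as a covariate, carotenoid genes (adjusted p = 0.0968, median log2 change 0.48 in place of 0.76), chloroplast-encoded genes (0.426, 0.14 in place of -2.46, though the share includes them), embryo storage genes (0.189, -0.42 in place of -1.65) and PIF1 (0.352, -0.51 in place of -0.73) lost their calls. So did HB-2 (0.691, 0.23 in place of 0.59), up from 10.09 ± 1.1 to 15.8 ± 2.5, and YUC8 (0.98, -0.01 in place of -0.47), down from 7.97 ± 1.11 to 5.46 ± 0.731. The calls of these 2 genes also ended when 1 of some libraries was left out. HB-2 lost its call without WT hook replicate 2 (adjusted p = 0.0549), WT hook replicate 3 (0.0544) or pifq hook replicate 2 (0.075), and also after median-ratio scaling (0.0757). YUC8 lost its call without WT hook replicate 1 (0.0677), WT hook replicate 3 (0.0544) or pifq hook replicate 1 (0.066). Over all genes, 5434 of the 11738 calls in hooks were kept in the same direction with the organelle-encoded share as a covariate.

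Hypocotyls were compared to ask what the long stem of a dark-grown seedling expresses without these factors. Auxin response genes rose there. Of the 17 Aux/IAA and GH3 genes, 12 rose, 1 fell and 4 were not called (13 rose and 1 fell adjusted over the list alone; adjusted p = 0.51 with an estimated correlation). IAA1 rose from 5.71 ± 1.01 to 28.6 ± 10.4 and IAA6 from 3.84 ± 3.28 to 31.8 ± 7.87. Of the 22 SAUR genes, 17 rose, 1 fell and 4 were not called (18 rose and 1 fell adjusted over the list alone; adjusted p = 0.523 with an estimated correlation). SAUR50 rose from 13 ± 3.01 to 43.2 ± 2.98 and SAUR62 from 2.23 ± 1.2 to 12.5 ± 1.68, while SAUR17 fell from 7.51 ± 5.06 to 0.122 ± 0.211. The auxin synthesis genes YUC5, YUC8 and YUC9 fell, from 4.04 ± 0.448 to 0.289 ± 0.0397, from 3.83 ± 0.357 to 1.74 ± 0.534 and from 4.82 ± 1.65 to 0.747 ± 0.546. They belong to a list that was not called (adjusted p = 0.0796), with 5 rises and 5 falls. After median-ratio scaling that list gave 4 rises and 9 falls. The cell wall list was not called (9 rises, 7 falls, adjusted p = 0.349), its median of 0.19 standing against a test pointing downward. The expansin gene EXPA5 rose from 18.4 ± 2.65 to 320.0 ± 31.8, and EXPA16 fell from 64.6 ± 13.8 to 2.15 ± 0.952.

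Genes induced by PIFs in the literature fell as a list in hypocotyls (5 rose, 12 fell and 5 were not called; 7 rose and 12 fell adjusted over the list alone; adjusted p = 0.453 with an estimated correlation). HFR1 fell from 44.3 ± 6.56 to 3.18 ± 0.543 and XTH15 from 258 ± 112 to 13.6 ± 2.03, while HB-2 rose from 4.45 ± 1.49 to 16.7 ± 3.44 and PRE1 from 7.63 ± 5.01 to 53 ± 6.63. Of the ethylene and hook genes, 4 rose, 15 fell and 3 were not called (adjusted p = 0.432 with an estimated correlation). HLS1 fell from 7.37 ± 2.93 to 1.51 ± 0.659 and the ethylene receptor gene ETR2 from 21.3 ± 2.86 to 4.52 ± 1.69. Gibberellin genes were not called (6 rises, 8 falls, adjusted p = 0.119), with a median of 0.06 and a mean of -0.20, but GASA4 fell from 2365 ± 347 to 463 ± 31.9. Brassinosteroid genes were not called (3 rises, 5 falls, adjusted p = 0.0713, median -0.14), with 2 rises and 9 falls after median-ratio scaling. They were called downward without WT hypocotyl replicate 2 (0.0449, median -0.27) or pifq hypocotyl replicate 3 (0.0385, median -0.23) and with the organelle-encoded share as a covariate (0.0345, median -0.23). Light signalling regulators were not called (adjusted p = 0.847). They gave 14 rises and 8 falls, or 8 rises and 11 falls after median-ratio scaling, and a median of 0.25 under a test pointing downward. BBX25 rose from 5.5 ± 2.15 to 64.3 ± 1.37.

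Photosynthesis genes of the hypocotyl rose from lower levels. LHCB1.4 rose from 18.3 ± 8.07 to 939 ± 196. Of the 20 light-harvesting genes, 17 rose, 1 fell and 2 were not called (18 rose and 1 fell adjusted over the list alone; adjusted p = 0.492 with an estimated correlation). All 30 photosystem and electron transport genes rose (adjusted p = 0.434 with an estimated correlation), PSAN from 32.1 ± 3.47 to 245 ± 49.9. Of the chlorophyll genes, 22 rose, 3 fell and 3 were not called (adjusted p = 0.547 with an estimated correlation). HEMA1 rose from 31.2 ± 5.23 to 144 ± 25.1, CHLH from 37.7 ± 18.1 to 218 ± 40.4 and PORC from 8.8 ± 2.27 to 22.6 ± 5.98, while PORA fell from 215 ± 12 to 14 ± 5.86 and PORB from 345 ± 27.7 to 137 ± 41.4. Calvin cycle genes rose as a list (13 rose, 1 fell and 6 were not called; 15 rose and 1 fell adjusted over the list alone; adjusted p = 0.574 with an estimated correlation). Carotenoid genes rose as a list (9 rose, 1 fell and 5 were not called; adjusted p = 0.574 with an estimated correlation). Chloroplast-encoded genes were called downward (2 rose, 9 fell and 108 were not called; 0 rose and 0 fell adjusted over the list alone; adjusted p = 0.716 with an estimated correlation). Their median log2 change was -0.29, but 0.51 without pifq hypocotyl replicate 3 and between -0.88 and -0.05 without any 1 of the other hypocotyl libraries. The call was lost without pifq hypocotyl replicate 3 (adjusted p = 0.262), after median-ratio scaling (0.271, median -0.50) and with fry (0.735), and with the organelle-encoded share as a covariate the list was called upward (0.00582, median 0.84). That share includes these genes, so the last fit does not test them.

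Cell cycle genes of the hypocotyl rose, as 16 rose, 0 fell and 1 was not called (adjusted p = 0.27 with an estimated correlation), KN from 8.05 ± 1.15 to 23.2 ± 2.72. Of the stomatal markers, 9 rose, 0 fell and 2 were not called (adjusted p = 0.51 with an estimated correlation). Flavonoid genes were not called as a list (8 rises, 1 fall, adjusted p = 0.207; 9 rose and 3 fell adjusted over the list alone), but DFR rose from 0.141 ± 0.0905 to 11.4 ± 3.86. Clock genes were not called (7 rises, 7 falls, adjusted p = 0.435), with a median of 0.26 under a test pointing downward. LHY rose from 11.1 ± 0.832 to 133 ± 29.9, and ELF4 fell from 48.7 ± 6.36 to 4.89 ± 2.31. Seed reserve genes fell as a list, with 1 rise, 6 falls and 5 not called (adjusted p = 0.547 with an estimated correlation). After median-ratio scaling 1 of them rose and 9 fell. Embryo storage genes also fell as a list, with 1 rise, 3 falls and 4 not called (adjusted p = 0.547 with an estimated correlation). Xylem markers fell as a list relative to other genes (0 rose, 1 fell and 9 were not called, adjusted p = 0.523 with an estimated correlation), with 8 falls after median-ratio scaling. Their median log2 change was -0.22, beside 0.171 for all genes tested. FLA11, a secondary wall gene, fell from 77.5 ± 10.4 to 47.9 ± 3.79. Shoot epidermis markers rose (2 rose, 0 fell and 1 was not called; 3 rose and 0 fell adjusted over the list alone; adjusted p = 0.51 with an estimated correlation), the epidermal regulator ATML1 from 24.9 ± 1.72 to 60.7 ± 4.12. That list call (adjusted p = 0.0483) was lost without organelle-encoded genes (0.052), with the stricter filter (0.0543), with a replicate block (0.0577) and in 10 fits that left out 1 library (0.0526 to 0.0615). Meristem markers were not called (4 rises, 0 falls among 8, adjusted p = 0.229), but the stem regulator KNAT1 rose from 48 ± 9.01 to 126 ± 29.3. Of 4 root markers 0 were called (adjusted p = 0.17).

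Across all genes tested in hypocotyls, 6939 were higher in pifq, 1593 of them by at least 2-fold. Another 3198 were lower, 1013 of them by at least 2-fold, and 9212 were not called. AT2G34700, an extensin family gene, fell from 182 ± 38.5 to 2.87 ± 1.22, and AZI1, a lipid transfer protein gene, from 994 ± 99.8 to 19.3 ± 10.6. Higher genes were 68.5% of the calls as deposited and 46.4% after median-ratio scaling, where 4528 were higher and 5228 lower, and the median log2 change moved from 0.171 to -0.026. With the organelle-encoded share as a covariate, 6 lists lost their calls in this organ, mostly with a similar median log2 change, so these losses do not show that the share explains the changes. They were Calvin cycle (adjusted p = 0.0761, median 0.67 in place of 0.84), carotenoid (0.129, 0.45 in place of 0.43) and stomatal genes (0.0729, 0.72 in place of 0.86). The others were seed reserve (0.0761, -0.18 in place of -0.23), xylem (0.0658, -0.16 in place of -0.22) and embryo storage genes (0.113, -1.17 in place of -1.54). Embryo storage genes lost their call also after median-ratio scaling (0.204) and with limma-voom (0.373), where the medians were -1.62 and -3.36, and carotenoid genes after median-ratio scaling (0.0589, median 0.22). With fry, seed reserve (0.0744), xylem (0.0722) and embryo storage genes (0.0557) were not called.

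Several calls of the hypocotyl ended when 1 of some libraries was left out, some with a similar and others with a smaller fold change. Carotenoid genes, with a median log2 change of 0.43, or 0.44, 0.40 and 0.39 in these fits, lost theirs without WT hypocotyl replicate 1 (adjusted p = 0.0585), WT hypocotyl replicate 3 (0.0784) or pifq hypocotyl replicate 3 (0.111). Embryo storage genes, with a median of -1.54, lost theirs without WT hypocotyl replicate 2 (0.187, median -0.16) or pifq hypocotyl replicate 1 (0.055), and seed reserve genes without WT hypocotyl replicate 2 (0.123, median -0.16 in place of -0.23). Xylem markers, with a median of -0.22, lost theirs without WT hypocotyl replicate 2 (0.13, median -0.13) or pifq hypocotyl replicate 1 (0.0859, median -0.18). HY5 fell from 49.8 ± 9.72 to 36 ± 3.15, a log2 change of -0.44. That call was lost without WT hypocotyl replicate 1 (0.139, -0.29), pifq hypocotyl replicate 1 (0.087, -0.38) or pifq hypocotyl replicate 3 (0.0547, also -0.44), in a fit of only the 6 libraries compared (0.0507) and with the organelle-encoded share as a covariate (0.0527, -0.47). PIL1 was not called (3.88 ± 1.05 and 5.8 ± 2.01, adjusted p = 0.0914), except without WT hypocotyl replicate 3 (0.0399) or pifq hypocotyl replicate 1 (0.047). IAA19 was not called either (43.2 ± 22.1 and 75.3 ± 5.79, adjusted p = 0.0578), except without WT hypocotyl replicate 3 (0.0216), WT cotyledon replicate 2 (0.0401) or WT cotyledon replicate 3 (0.0205).

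**Figure D4:**
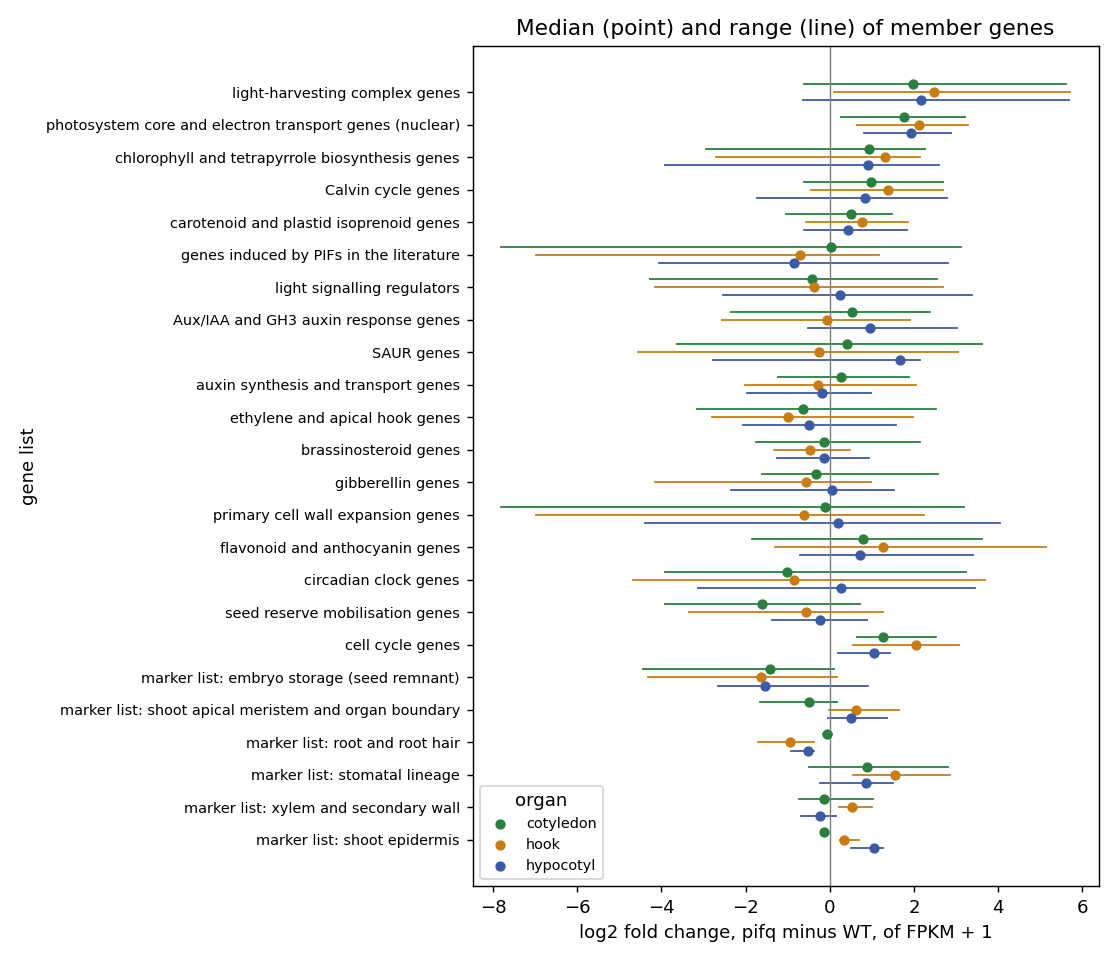
Median (point) and range (line) of the log2 fold change of FPKM + 1, pifq minus WT, of the member genes of 24 lists, by organ in colour, with the chloroplast-encoded list left out. Light-harvesting medians lie at 1.99 in cotyledons, 2.47 in hooks and 2.17 in hypocotyls, and ethylene and hook gene medians at -0.63, -0.98 and -0.48.

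Many genes moved one way in all 3 organs. HLS1, HFR1, PORA, SAUR17 and XTH15 fell in each, and PIF7, LHCB1.4, HEMA1, SAUR50 and KN rose in each. In total 2675 genes were higher in all 3 organs and 1611 lower, 4286 together. Independent calls would share 620.0 and 271.8. The 3 comparisons share no library, but come from 1 fit with 1 estimate of spread per gene. Calls can therefore coincide above these numbers without a shared effect. Across genes, which are not independent replicates, the log2 changes of cotyledon and hook had a Pearson's r of 0.711 and a Spearman's rho of 0.612. Those of cotyledon and hypocotyl had 0.535 and 0.533, and those of hook and hypocotyl 0.670 and 0.655.

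Differences of the pifq effect between organs were tested as interactions, since a call in 1 organ alone shows no difference. EXPA8, an expansin gene, rose in cotyledons from 9.64 ± 8.16 to 32.3 ± 3.19 and fell in hooks from 229.9 ± 29 to 56.9 ± 25.2. Its effect in hooks minus cotyledons was -4.00 (log2; adjusted p = 5.2e-05). PRXCB, a peroxidase gene, rose in cotyledons from 5.12 ± 0.89 to 20.2 ± 1.9 and fell in hypocotyls from 384 ± 20.02 to 87.4 ± 13.9, a difference of -3.93 (adjusted p = 7.4e-07). YUC5 rose in cotyledons from 0.16 ± 0.0319 to 2.37 ± 1.2 and fell in hypocotyls, a difference of -3.45 (adjusted p = 1.9e-07). STM differed between hooks and cotyledons by 2.14 (adjusted p = 8.8e-05) and TAA1 by -2.06 (adjusted p = 1.6e-05). Whether cotyledon and hook pieces of the 2 genotypes held equal shares of meristem tissue was not tested. For LHCB1.4 no pair of organs was called apart (lowest adjusted p = 0.875). The effect on the Aux/IAA and SAUR lists was higher in hypocotyls than in hooks, where neither list was called, by median log2 differences of 1.19 and 1.71 (adjusted p = 0.00117 and 3.9e-05, or 0.497 and 0.501 with an estimated correlation).

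Interactions were called for 8016 genes between hook and cotyledon, 8843 between hypocotyl and cotyledon and 5627 between hypocotyl and hook. In total 11624 genes, YUC5, STM, TAA1 and HLS1 among them, differed between some of the organs. The effect was higher in hooks than in cotyledons for 73.6% of the calls as deposited and 39.7% after median-ratio scaling. It was higher in hypocotyls than in cotyledons for 75.8% and 39.99%, and higher in hypocotyls than in hooks for 57.0% and 49.3%. Genes called in opposite directions numbered 1259 in hook and cotyledon, 1266 in hypocotyl and cotyledon and 590 in hypocotyl and hook. Independent calls would give 3642, 3235 and 2839.

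In WT the organs were compared to ask what each expresses in the dark. GASA4 stood at 12200.4 ± 1493 in hooks against 1078 ± 397 in cotyledons and 2365 ± 347 in hypocotyls. ADF9, an actin-depolymerising factor gene, stood at 86.4 ± 10.7 in hooks against 8.36 ± 2.04 and 16 ± 2.45. ATPMEPCRD, of the pectin methylesterase inhibitor family, marked hypocotyls with 944 ± 168 against 2.0 ± 1.88 in cotyledons and 5.98 ± 3.88 in hooks. The peroxidase gene AT2G37130 did so with 3313 ± 71 against 7.52 ± 2.83 and 26 ± 21.3. SEH, an epoxide hydrolase gene, marked cotyledons with 128 ± 8.59 against 28.1 ± 5.57 in hooks and 13.9 ± 3.3 in hypocotyls. Called genes numbered 11184 between hook and cotyledon (6556 higher in hook), 14312 between hypocotyl and cotyledon (7025 higher in hypocotyl) and 12532 between hypocotyl and hook (4416 higher in hypocotyl). In this order the higher genes were 58.6%, 49.1% and 35.2% of calls as deposited, and 49.4%, 52.8% and 50.0% after median-ratio scaling.

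In pifq the same organ comparisons ask which of these contrasts remain without the 4 factors. GASA4 was still highest in hooks on the deposited scale, but its log2 difference between hook and cotyledon was 0.63 (adjusted p = 0.0141), compared with 3.55 in WT. The median of all genes in that pifq contrast was 0.377 as deposited and -0.034 after median-ratio scaling. The lead of GASA4 over cotyledons therefore depends on the scale. ATPMEPCRD in hypocotyls was 142 ± 10.7 and AT2G37130 228 ± 71.4, each still above both other pifq organs (adjusted p = 2.6e-05 and 3.5e-05 against hooks). SEH was 53.4 ± 1.77 in cotyledons, 25 ± 4.69 in hooks and 15.8 ± 2.91 in hypocotyls. ADF9 was not called between hypocotyl and hook (adjusted p = 0.667). Called genes numbered 12523 between hook and cotyledon, 13912 between hypocotyl and cotyledon and 12509 between hypocotyl and hook. Of the first, 10326 were higher in hook (82.5%, or 43.4% after median-ratio scaling). Of the second, 9584 were higher in hypocotyl (68.9%, or 51.9%), and of the third, 5241 (41.9%, or 52.5%).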

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

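Of the tests in this part, those of small RNA in cotyledons alone, of mitochondrial transcripts, of chloroplast-encoded transcripts in hypocotyls, limma-voom, median-ratio scaling and the binomial test on pifq hook replicate 2 were chosen only after the result was seen.

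The effect of pifq differed between organs, by tests of the difference itself, for 11624 genes over all organs. Between hook and cotyledon there were 8016 such genes, between hypocotyl and cotyledon 8843 and between hypocotyl and hook 5627. Other splits of the libraries, 100 for each, gave at most 8351, 3758, 6150 and 4230 genes, and 1 of 100, the real one, was as large in each case. Splits other than the real one mix WT and pifq in at least 1 organ, but can keep the real labels in another. Those that keep them set a full genotype effect in 1 organ beside a mixed one, which can itself give many calls. The splits therefore stand neither for no genotype effect nor for an equal effect in all organs. They cannot decide whether the organ differences arose by chance.

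In 31 of 75 list tests the effect differed between 2 organs with camera's preset correlation, and in 0 with an estimated correlation, where 4 had an unadjusted p under 0.05. After median-ratio scaling the medians stayed on the same side of 0 in all 31, and 28 were called. That scaling moved the median difference of all genes from 0.25 to -0.07 for hooks minus cotyledons, from 0.28 to -0.10 for hypocotyls minus cotyledons and from 0.02 to -0.04 for hypocotyls minus hooks. Hooks minus cotyledons, the median log2 differences, with the value after scaling in parentheses, were -0.20 (-0.50) for Aux/IAA and GH3, -0.82 (-1.06) for SAUR, -0.71 (-1.06) for auxin synthesis and transport and -0.37 (-0.73) for brassinosteroid genes. They were -0.13 (-0.48) for ethylene and hook, -0.77 (-0.96) for PIF-induced, -0.71 (-0.98) for gibberellin and -0.45 (-0.81) for cell wall genes. Cell cycle genes gave 0.63 (0.27) there and meristem and boundary markers 1.35 (1.12), with the share of meristem tissue in each piece not tested. Hypocotyls minus cotyledons, they were -0.28 (-0.73) for auxin synthesis and transport, -0.57 (-0.86) for cell cycle and -0.46 (-0.73) for stomatal genes, and 2.58 (2.296) for chloroplast-encoded, 0.99 (0.80) for meristem and 1.43 (0.97) for seed reserve genes. The calls lost after scaling were Aux/IAA and GH3 (adjusted p = 0.24) and cell cycle genes (0.0689) for hooks minus cotyledons and stomatal genes (0.153) for hypocotyls minus cotyledons.

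Hypocotyls minus hooks, the pifq effect on growth and light lists was higher: 1.19 for Aux/IAA and GH3, 1.71 for SAUR, 0.49 for ethylene and hook, 0.96 for PIF-induced, 0.67 for gibberellin, 0.64 for light signalling and 0.79 for cell wall genes. These are medians of differences per gene, not of levels, and can part from the list medians. The PIF-induced list had a median log2 change of -0.72 in hooks and -0.86 in hypocotyls. Chloroplast-encoded genes gave 2.11 and seed reserve genes 0.39. Lists with a lower effect were Calvin cycle genes with -0.50, cell cycle genes with -1.09, chlorophyll genes with -0.40, flavonoid genes with -0.59, stomatal markers with -0.86 and xylem markers with -0.89.

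Single genes with the largest differences of effect among called genes of at least 10 CPM, or with opposite calls, were these. Hooks minus cotyledons on the log2 scale, AT5G04120 gave -5.88, AT3G54830, of an amino acid transporter family, -5.60, CLE5 -5.05, CLE6 -4.81, EXPA9 -4.68, the transcription factor gene UPB1 -4.66, AT5G44020 -4.32 and EXPA8 -4.00. CLE6 is listed at 0 in all 3 pifq hook libraries. With limma-voom, AT5G04120 (adjusted p = 0.0513) and UPB1 (0.137) lost their calls, while the other alternatives gave 9.4e-07 to 0.00021 and 4.7e-06 to 0.00255. Hypocotyls minus cotyledons, AT2G34700 gave -5.62, the lipase-like gene TLL1 -5.46, AT2G25150 -5.38, AT4G37220, of a cold acclimation family, -5.30, AT1G27030 -3.99, PRXCB -3.93 and AT5G42530 5.01. The chloroplast genes ATCG01120 and ATCG00110 each gave 5.41. Hypocotyls minus hooks, ENSRNA049494991 gave 6.88, ATCG00820 6.70, ATCG00760 6.24, ATCG00780 6.11, ATCG00770 6.05 and ATCG00800 5.997. Of the other 163 named genes, 125 were called for some difference between organs. Groups of 3 are too small for the outlier test.

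The first pattern weighed is the fall of organelle-encoded transcripts in pifq cotyledons and hooks. Nuclear small RNA was used to ask about less carry-over of RNA without a poly(A) tail in both organs. Its larger pifq to WT ratio of the 2 organs was 0.998, in hooks, against that prediction. But small RNA sums followed organelle sums poorly. In pifq hypocotyl replicates 2 and 3 they were 43.8 and 32.3, with chloroplast-encoded sums of 4307 and 316. The hook ratio therefore cannot decide on such carry-over. In cotyledons alone the small RNA ratio was 0.216 (131.5 to 28.4 depth-scaled reads summed over 168 genes), so such carry-over may account for part of the cotyledon fall. That fall was larger, to 0.0632 of WT for chloroplast-encoded and 0.0183 for mitochondrion-encoded transcripts, and the small RNA loci can overlap longer transcripts. A change of plastids alone is argued against by mitochondrion-encoded transcripts, at 0.0183 of WT or less in both organs. A fall of similar size in every pifq library is argued against by chloroplast-encoded transcripts in hypocotyls. Their pifq to WT ratio of 1.18 there was 0.654 or above without any 1 library, against 0.0822 or below in cotyledons and hooks, and pifq hypocotyl replicate 3 alone lay below every WT hypocotyl library. Library preparation in hooks and a loss of RNA of both organelles in these organs of pifq stay open, as untested.

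The second pattern is pifq hook replicate 2, which lay nearer the hypocotyls than the other pifq hook libraries on the first principal component. More hypocotyl tissue in it cannot be told apart from other causes. In that library 37 genes lower in WT hypocotyls lay a median 0.0766 of the way to pifq hypocotyls, with quartiles of -0.227 and 0.379 and 22 of 37 on that side (binomial p = 0.324). For 640 genes higher there the median was 0.118, with quartiles of 0.0588 and 0.174 and 599 on that side. The criterion first written, on the medians alone, would have gone with that tissue. Less cotyledon tissue may contribute, since 19 genes higher in WT cotyledons stood at a median 0.604 of the other pifq hook libraries, 15 of them lower (binomial p = 0.0192). Genes of 1 library are not independent trials, so these binomial p-values are descriptive only. Dissection and a biological difference between these seedlings stay open, as untested.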

How the results depend on the processing

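The tests with median-ratio scaling, limma-voom on recovered reads, the organelle covariate and the 2 libraries left out together were chosen only after the result was seen. Against 4528 higher and 5228 lower genes in hypocotyls after median-ratio scaling and 4425 and 5211 with limma-voom at its factors, the deposited scale gave 6939 and 3198. The organelle covariate, which moves with genotype, left 2691 and 3367 genes in cotyledons, 3996 and 1964 in hooks, and 2148 shared by all 3 organs. It also turned GASA6 in hooks to -0.036 (adjusted p = 0.97) and MYB12 in hooks to 0.38 (0.589), so both lost their calls. Chloroplast-encoded genes in hypocotyls, themselves part of that share, turned to 0.84. Camera with an estimated correlation called 0 lists, where 6 had an unadjusted p under 0.05, and fry 56. Under fry, light signalling genes in hypocotyls pointed upward with a median of 0.25. Chloroplast-encoded genes in hypocotyls ranged from -0.88 without pifq hypocotyl replicate 2 to 0.51 without pifq hypocotyl replicate 3, and gave 0.51 without that library and pifq hook replicate 2. The cause was not tested for any of these changes.

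Over all settings, named genes gave 8283 values on the same side of the threshold, 152 calls lost, 9 gained and 2 reversed, and lists 2052, 91, 22 and 4. Reversed means a turned direction with a call in either the main or the other fit. The 2 reversed genes were not called after turning. Leaving out 1 library gave 4233 to 4797 higher and 6217 to 6950 lower genes in cotyledons, 6399 to 7200 and 4058 to 4755 in hooks, and 6116 to 7000 and 2749 to 3255 in hypocotyls. Where an arm then held 2 libraries, the pooled spread assumes that they vary like the other groups. Shoot epidermis markers in hypocotyls lost their call in 10 such fits (adjusted p of 0.0526 to 0.0615). The replicate numbers were not taken to pair the libraries in the main fit, since the labels state no pairing. The correlations lean toward some pairing, which that fit ignores. Within an organ 9 pairs of equal number had a median r of 0.0887 (4 over 0.1), with -0.0435 for unequal numbers. Of 18 libraries, 10 correlated best with their own number. Across organs of 1 genotype the median was 0.0898 over 18 pairs (9 over 0.1), with -0.0177 for unequal numbers. Between pifq hook and hypocotyl all 3 pairs lay over 0.1 (0.116 to 0.201), and the block there gave 12426 genes in place of 12509. A replicate block gave 4676 and 6794 genes in cotyledons, 7032 and 4573 in hooks and 6852 and 3163 in hypocotyls. With it shoot epidermis markers in hypocotyls (adjusted p = 0.0577) and MYB12 in hooks (0.0597) were not called, and no other list or named gene changed its call. The planned count-based fits with TMM, RLE or library size, DESeq2 and limma-voom with TMM are not reported, since the deposited values are not counts, and limma-voom on reads recovered through reference exon lengths stands in their place. They were run once on those reads: in hypocotyls each called more genes lower than higher, as after median-ratio scaling, except the fit with library size alone, which called more higher, as on the deposited scale.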

Other observations

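The test of neighbouring genes in this part concerns a pattern noticed only after its values were seen, and the tests of families and of median-ratio scaling were chosen only after the result was seen.

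Gene families of at least 15 members show what else moved. Of 28 histone genes, 21 rose in pifq cotyledons and 1 fell (24 rose after median-ratio scaling), and in hooks 23 rose and 1 fell (22 after scaling), beside the cell cycle genes that rose in the same organs. Of 25 NPH3 family genes, 15 rose in cotyledons and 2 fell (18 rose after scaling). In hooks, 15 of 17 pseudouridine synthase genes rose (11 after scaling) and 18 of 26 OB-fold genes (14 after scaling). Of 186 RING/U-box genes, 73 fell and 27 rose in hooks (93 fell after scaling), and 68 fell and 22 rose in hypocotyls (104 fell after scaling). Of 144 pentatricopeptide repeat genes, 85 fell and 8 rose in cotyledons (65 fell after scaling), while 63 rose and 4 fell in hooks (40 rose after scaling), a family effect not called there (adjusted p = 0.0651). With an estimated correlation no adjusted p of these families lay below 0.953.

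The third pattern is AT1G72290 (chromosome 1, 27215787 to 27216857, TAIR10.1), a Kunitz-type protease inhibitor gene and marker of the WT hook. It is listed at 0 in all 9 pifq libraries and at 3.56 to 33.6 in all 9 WT libraries. A deletion in the pifq line that reaches a neighbour is argued against by the nearest expressed genes, ERO1 and PSY1R, which stood at 1.57 or above in every pifq library. A smaller lesion, a linked difference between the lines and a loss of expression without these factors stay open, and no biological explanation was tested. AT5G49860 is the other gene with a WT mean of at least 1 at 0 in every pifq library and above 0 in every WT library, and MYB29 the reverse, each named after its values were seen.

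For comparisons of 3 libraries with 3, the 10 splits cannot give a share under 0.1, and in each 1 of 10 was as large. The real and highest other counts were 4718 and 0 higher, 6847 and 0 lower in cotyledons, 7090 and 0 higher, 4648 and 5 lower in hooks, and 6939 and 82 higher, 3198 and 2 lower in hypocotyls. In WT they were 11184 and 1 for hook against cotyledon, 14312 and 0 for hypocotyl against cotyledon and 12532 and 24 for hypocotyl against hook. In pifq they were 12523 and 1, 13912 and 0, and 12509 and 2. For the 4286 genes called one way in all 3 organs, 1 of 100 splits was as large and the highest other gave 0. That argues against chance labels of genotype, but does not test whether organs share calls by chance. For the list tests 4 of 100 splits, the real one included, gave at least its 45 calls and the highest other gave 46. That count, at the preset correlation, therefore barely separates the real labels from other splits, which can keep the real labels in some organs. An estimated correlation called 0 lists (6 at an unadjusted p under 0.05) and fry 56.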
